A study of Gallus gallus with 16 samples.

How the data were processed

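RNA was sequenced from 16 chicken embryos, 1 library per embryo. Per the labels, each library came from a dissected piece holding the spinal cord, taken between the middle of the neck and the hind edge of the forelimb. Eggs had received nicotine (30 ng/ml, adjusted to egg weight) or vehicle before incubation, and embryos were taken at day 5 or day 7. This gives 4 groups of 4 embryos, which the labels describe as biological replicates. The labels name no sequencing batch, embryo sex or RNA quality value.

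The count matrix holds whole-number read counts per locus as the authors deposited them, 1 column per library, with no normalisation. The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.4.4, HISAT2 2.0.5, Bowtie2 2.3.2, StringTie 1.3.3b and DESeq2, without saying which step each served. Genome build, annotation and strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes cannot be separated and no coordinates are given. The matrix has 26943 loci, of which 18258 carry an assembled locus identifier and 8685 a gene identifier. Loci with a gene identifier hold 0.334% of all counts. Gene symbols came from the authors' comparison tables, which share 7138 identifiers with the matrix and pair 1141 of its loci with a symbol. No per-sample column was left unmapped. Total counts ran from 21801247 to 29002315 per library.

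The authors also deposited 5 tables of their own comparisons, each with 21357 identifiers, 9225 of them with a symbol. Each table gives the authors' log2 fold change, the fold as a linear ratio, a p-value and an adjusted p-value. They hold no expression level and no standard error. In 4 of the tables an adjusted p of exactly 1 is also given to loci with small p-values, so it is read there as no adjusted value. The table of nicotine at day 7 gives it only where p is 1. Each table was matched to its contrast across 3104 loci shared with the matrix: the correlation of its log2 fold changes with those of DESeq2 on the matrix was 0.891 to 0.961 for the contrast it is named for, and lower for the other contrasts. With a covariate for 4 libraries that lack 57 loci it was 0.990 to 0.992, so the tables appear to hold a fit with such a term, which the sources do not name. Genes are not independent replicates, so this correlation describes the tables only. The tables name most genes and the matrix does not, so values of named genes below come mainly from the tables, and each is credited to them.

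Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalisation, quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). All 16 libraries entered a single fit of the 4 group means, and 18394 loci, 756 with a symbol, were tested. The 5 contrasts were nicotine against vehicle at each day, day 7 against day 5 in each treatment, and the difference of the nicotine effect between days. Levels are CPM, the counts of a library scaled by its total and TMM factor, as mean ± SD over 4 libraries. DESeq2 1.42.0 was the alternative tool. The steps were tested on simulated counts with 100 loci changed 2-fold and 100 changed 1.5-fold among 18394. Changed loci were drawn above a minimum mean level, which some named loci below do not reach. All groups otherwise had the same mean and loci were drawn independently, so structure among the real libraries was not covered. At day 5 edgeR recovered 57% of the former and 14% of the latter and called 2 other loci, and DESeq2 recovered 75% and 40% and called 38 others. At day 7 edgeR recovered 55% and 25% and called 4 others, and DESeq2 recovered 69% and 42% and called 33 others. For the difference between days edgeR recovered 44% and 5% and called 2 others, and DESeq2 recovered 58% and 14% and called 40 others.

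Before the data were examined, the groups, the contrasts, the main test, the alternatives, the rule for named genes and 37 gene lists were fixed. The rule for named genes took, per contrast, up to 10 genes with a symbol in each direction with the largest log2 fold change among those with an adjusted p under 0.05, at least 2 CPM in the higher group and no overlap of the groups. Where fewer than 5 passed in a direction, those with the smallest p were added and are said not to have passed. The rule also took up to 4 genes per list with the smallest p, and 4 nicotinic receptor subunits always. The tables give no level, so the CPM and overlap conditions could not be applied to them, and a limit of 10 on the size of the log2 fold change was added after the data were seen.

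The lists were nicotinic receptor subunits, motor neurons and cholinergic transmission, neural progenitors, neuronal differentiation and cytoskeleton, spinal interneuron transcription factors, synapse and neurotransmitter genes, astroglial genes, oligodendrocyte lineage, Sonic hedgehog pathway, Wnt pathway, BMP pathway and roof plate, Notch pathway, retinoic acid pathway, neural tube closure and folate metabolism, axon guidance, cell cycle, apoptosis and p53 targets, oxidative stress response, unfolded protein and integrated stress response, heat shock and immediate early genes, hypoxia and glycolysis, xenobiotic and nicotine metabolism, cholesterol synthesis, brachial Hox genes and posterior Hox genes. Markers of other cells and of sample quality were lists of erythroid cells, skeletal muscle, cartilage and sclerotome, connective tissue and meninges, endothelium, macrophages and leukocytes, dorsal root ganglia and neural crest, epidermis, notochord and floor plate, mitochondrially encoded genes, W-linked genes and ribosomal proteins. The planned list test on the matrix could not be run, since no list had more than 4 tested members there. In its place, limma 3.58.1 cameraPR was run on the signed z of the p-values in the authors' tables, a choice made after the data were seen. It used a preset inter-gene correlation of 0.01, lists with at least 5 measured members, named genes with an adjusted p under 1 as background, and Benjamini-Hochberg adjustment over lists. Measured here means having an adjusted p under 1 in the table of that comparison. The correlation could not be estimated from a table of p-values, so each call is also given at a preset of 0.05 where it ended there. Intervals of list medians are at least 95% and come from the order of the genes, taken as independent. The p of a list likewise measures spread over genes and not over embryos. Mitochondrially encoded genes and W-linked genes had fewer than 5 measured members in every comparison and were not tested, some other lists fell short in single comparisons, and the planned shares of counts from other cell types were not computed for the same reason.

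Gene span came from the RefSeq gene table of the GRCg7b assembly, matched by symbol, and the assembly behind the files may differ. It was found for 94.97% of the 756 tested loci with a symbol and for at least 96.4% of the named genes of each table. The long minus short score of a library is the median log2 CPM (prior count 2), centred on each gene's mean over all libraries, of the 221 longest of 663 such genes outside the sex chromosomes minus that of the 221 shortest. Measures of libraries were compared by two-sided exact permutation tests of 4 against 4 libraries, which cannot give a p under 0.0286, with Benjamini-Hochberg adjustment over 8 tests. Replicates were compared within each group by a chi-square test of their counts, whose value per degree of freedom was 16.0 to 64.1, so no pair of libraries differed as little as sampling noise. Other normalisations, filters, tools, library sets, a replicate block and leaving out each library in turn were tried as alternatives.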

Results

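Gene expression was measured by RNA sequencing in the spinal cord region of chicken embryos at day 5 and day 7, after nicotine (30 ng/ml) or vehicle was injected into the egg before incubation. There were 4 vehicle and 4 nicotine embryos at each day. Total counts were 21801247 to 29002315 per library. The series asks how nicotine affects the development of the neural tube, through treatment and days of incubation. Mean totals at day 5 differed between nicotine and vehicle by less than their spread, at 24756200 ± 3070560 and 24726800 ± 2247010 (SD, n = 4 each, exact permutation p = 0.971, adjusted p = 0.971). At day 7 they were 24885700 ± 2742280 and 25419500 ± 2465820 (SD, n = 4 each, exact permutation p = 0.771, adjusted p = 0.882).

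Embryonic day was the main difference among the libraries. The first principal component held 24.1% of the variance and separated the 8 libraries of day 5 from the 8 of day 7. The other leading component held 14.9% and set apart 4 libraries, 1 in each group, at -75.3 to -48.4, from the other 12 at 5.73 to 29.7. The same 4 libraries had under 0.05 CPM of 57 loci that stood at 0.5 CPM or more in each of the other 12.

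**Figure D1:**
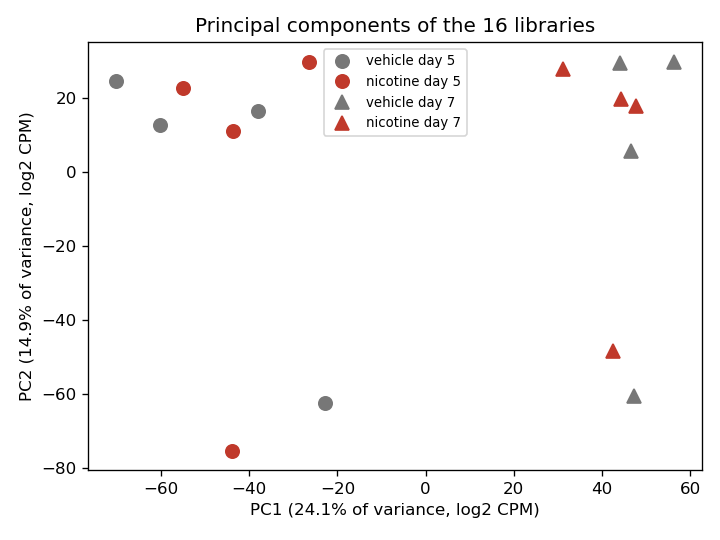
Principal components of log2 CPM for the 16 libraries, with grey for vehicle, red for nicotine, circles for day 5 and triangles for day 7. Days separate along the horizontal axis (24.1% of variance), and 1 library of each group lies below -48 on the vertical axis (14.9%).

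Nicotine and vehicle embryos of day 5 were compared first. In the authors' deposited table, 322 loci differed, 90 higher and 232 lower with nicotine, and 213 of them carried a symbol. ISL1, a transcription factor of motor and sensory neurons, rose there by 0.65 on the log2 scale (adjusted p = 0.0338 in the authors' deposited table), and RSPO1, a secreted activator of Wnt signalling, by 0.96 (adjusted p = 0.0181). They were the only calls among 6 genes of motor neurons and cholinergic transmission and 13 of the Wnt pathway in the authors' deposited table, against 1 and 2 higher and 0 and 1 lower adjusted over each list alone. RYR3, a calcium release channel, fell by 1.10 in the authors' deposited table (adjusted p = 0.000334). None of these calls was shared by edgeR on the count matrix, which called 0 loci (smallest adjusted p = 0.217). It had 2747 loci at an unadjusted p under 0.05, against 919.7 if p were uniform. Other splits of the day 5 libraries reached 3915, and 7 of 35 splits, counting the real one, were as large. DESeq2 on the same matrix called 264, 84 higher and 180 lower. That count moved by over 1.5 times without each of the 8 libraries of day 5. DESeq2 called 35, 57, 67 and 91 without vehicle replicate 3, nicotine replicate 3, vehicle replicate 1 and nicotine replicate 2. It called 467, 700, 867 and 1181 without nicotine replicates 1 and 4 and vehicle replicates 2 and 4. Without vehicle replicates 3 and 1 lower loci were no longer in excess (17 lower and 18 higher, 29 lower and 38 higher).

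In the authors' deposited table genes of neuronal differentiation were higher as a list at day 5, while a call for neural progenitors depended on the settings of the test. Neither list was tested on other splits of the libraries. Over the 10 measured genes of neuronal differentiation and cytoskeleton the median log2 fold change in the authors' deposited table was 0.45 (cameraPR adjusted p = 0.00467). None of the 10 passed over all genes in the authors' deposited table, and 3 passed as higher when adjusted over the list alone. The neurofilament gene NEFM stood at 0.59 (adjusted p = 0.0841), NEFL at 0.45 (adjusted p = 0.0956) and the neuronal splicing factor RBFOX3 at 0.48 (adjusted p = 0.0914) in the authors' deposited table. Of 11 neural progenitor genes, 1 rose, the same number as adjusted over the list alone, and the list median in the authors' deposited table was 0.27 (cameraPR adjusted p = 0.0205). That gene was NKX6-1, a factor of the ventral neural tube, at 0.51 (adjusted p = 0.0348) in the authors' deposited table, with PAX6 at 0.51 (adjusted p = 0.264) and SOX9 at 0.44 (adjusted p = 0.262). The progenitor call ended at a preset inter-gene correlation of 0.05 (adjusted p = 0.0908) and after removal of a gene span trend (adjusted p = 0.116).

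Of the 29 lists tested at day 5, the other 27 did not pass. Epidermis, brachial and posterior Hox genes, erythroid cells, nicotinic receptor subunits and spinal interneuron transcription factors had fewer than 5 members with an adjusted value at day 5 and were not tested. After removal of the span trend the Sonic hedgehog pathway passed as higher (cameraPR adjusted p = 0.0234). Axon guidance then passed too (cameraPR adjusted p = 0.0495), with the test pointing up while the median was -0.04. The immediate early genes JUN and DUSP1 rose by 0.43 and 0.46 in the authors' deposited table (adjusted p = 0.0243 and 0.0414), as 2 of the 12 genes of heat shock and immediate early genes, or 3 adjusted over the list alone. Of 27 axon guidance genes, 2 fell over all genes and adjusted over the list alone: EPHA3, an ephrin receptor, at -0.66 and SEMA3C, a secreted guidance cue, at -0.71 in the authors' deposited table (adjusted p = 0.0213 and 0.00928). CSF1R, the receptor on which macrophages depend, fell by 0.46 in the authors' deposited table (adjusted p = 0.00694), as 1 of 5 genes of macrophages and leukocytes, also adjusted over the list alone. BMPR1A, a BMP receptor, fell by 0.49 in the authors' deposited table (adjusted p = 0.00694), as 1 of 10 genes of the BMP pathway and roof plate, also adjusted over the list alone. RARB, a retinoic acid receptor, fell by 0.36 in the authors' deposited table (adjusted p = 0.0191), as 1 of 7 retinoic acid pathway genes, against 1 lower and 2 higher adjusted over the list alone. SHMT1, of folate metabolism, rose by 0.48 in the authors' deposited table (adjusted p = 0.0122), as 1 of 21 genes of neural tube closure and folate metabolism, against 1 higher and 2 lower adjusted over the list alone. The nicotinic receptor subunits CHRNA4 and CHRNB2 stood at -0.03 and 0.35 in the authors' deposited table (adjusted p = 0.942 and 0.489), CHRNA3 stood at -0.01 without an adjusted value, and CHRNA7 was not listed under that symbol.

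The genes with the largest changes at day 5 were mixed in function. In the authors' deposited table, increases among the largest were those of SGCA, CELF2, RSPO1, TNS1, LMO3, DDIT4, PLXNB1, ISL1 and GJA4, at log2 0.64 to 1.10. The largest decreases in the authors' deposited table were of RYR3, LGR4, FTO, CLSTN2, ADGRG2, SOX6, CSRNP3, COL14A1, LAMB4 and EEA1, at log2 -1.10 to -0.82. Genes that were lower were long: in the authors' deposited table the genes called higher had a median span of 8.64 kb and those called lower 60.8 kb, and the rank correlation of span with the log2 fold change was -0.40 across 6974 genes. A long minus short score in the matrix, chosen after this was seen and taken from the same libraries, was -0.380 ± 0.375 in nicotine and 0.0791 ± 0.109 in vehicle libraries (SD, n = 4 each), an exact permutation p of 0.0286, the smallest this design can give, and 0.229 adjusted over 8 tests. Nicotine replicate 3 had the lowest score, at -0.924, and without that library the difference between nicotine and vehicle was -0.278 in place of -0.459.

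**Figure D2:**
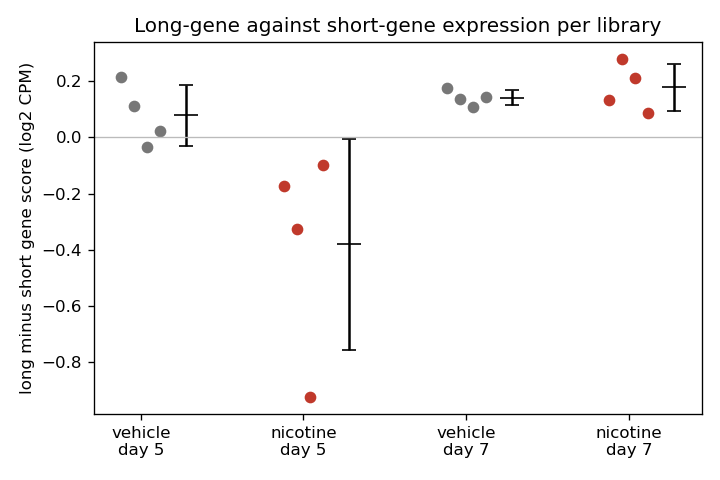
Long minus short gene score in log2 CPM of each library, with the mean and SD of each group of 4 beside its points. The nicotine libraries of day 5 lie between -0.924 and -0.0973, below the vehicle libraries of that day at -0.0338 to 0.216, while the groups of day 7 overlap.

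On the matrix alone, none of the named loci of day 5 passed with edgeR. LCP2 (ENSGALG00000002113), an adaptor protein of blood cells, had 2.85 ± 0.104 CPM in vehicle and 1.26 ± 0.187 CPM in nicotine libraries (SD, n = 4 each), a log2 fold change of -1.17 with a standard error of 0.27 (edgeR adjusted p = 0.217). GJB1 (ENSGALG00000005541), a gap junction protein, had 0.826 ± 0.425 CPM in vehicle and 2.32 ± 0.711 CPM in nicotine libraries (SD, n = 4 each), a log2 fold change of 1.49 with a standard error of 0.36 (edgeR adjusted p = 0.222). MLIP, HHIPL2, SYCP2 and SLC9A2 had the next smallest p among lower loci, at log2 -2.12 to -0.77 (edgeR adjusted p = 0.236 to 0.258). KCNS1, CNGA4 and FEV stood at log2 0.92, 1.55 and 1.76 (edgeR adjusted p = 0.222, 0.228 and 0.228). SLC4A5 had 0 counts in the 4 vehicle libraries and 0 to 21 in nicotine libraries, where its level was 0.600 ± 0.411 CPM (SD, n = 4). Its mean was 4.78-fold higher when the vehicle group is set to 3 counts per library (edgeR adjusted p = 0.226), but the groups meet at 0 counts. DESeq2 on all 16 libraries gave these loci no adjusted p, since its filter on low mean counts left them out. With a covariate for the 57 absent loci DESeq2 called GJB1, KCNS1, SLC4A5, CNGA4 and LCP2 (DESeq2 adjusted p = 0.00803 to 0.0472), and without nicotine day 5 replicate 3 it called SLC4A5 (DESeq2 adjusted p = 0.00138).

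At day 7, DLX1, DLX5, DLX6 and MMP11 were lower with nicotine and HOXC4 was higher. The authors' deposited table lists 84 loci, 47 higher and 37 lower, of which 18 carried a symbol. DLX1, DLX5 and DLX6, which pattern the forebrain, the face and the limb, fell, with log2 fold changes of -1.97, -2.02 and -2.80 in the authors' deposited table (adjusted p = 0.00171, 0.00422 and 0.00214). The other DLX genes listed, DLX2 and DLX3, stood at -1.88 and -1.58 in the authors' deposited table without passing (adjusted p = 0.348 and 0.121). MMP11, a matrix metalloproteinase, fell by 0.99 in the authors' deposited table (adjusted p = 0.000612). edgeR on the matrix called 0 loci at day 7 (smallest adjusted p = 0.0616), with 858 at an unadjusted p under 0.05 against 919.7 if p were uniform. Other splits of the day 7 libraries gave at most 867, and 2 of 35 splits, counting the real one, were as large. DESeq2 called 31, and edgeR restricted to the 8 libraries of that day called 5. With 1 library of that day left out DESeq2 called 24 to 71, with 71 and 48 without replicate 3 of vehicle and of nicotine.

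In the authors' deposited table epidermal genes were lower and brachial Hox and muscle genes higher as lists at day 7. The p of a list measures spread over genes and not over embryos, and no list was tested on other splits of the libraries. All 5 measured epidermis genes were summarised by a median of -0.58 in the authors' deposited table (cameraPR adjusted p = 6.18e-06), where 1 fell over all genes and 3 adjusted over the list alone. CDH1, the epithelial cadherin, was the gene that fell, at -0.61 (adjusted p = 0.032), with ESRP1 at -0.95 (adjusted p = 0.384) and EPCAM at -0.58 (adjusted p = 0.730) in the authors' deposited table. Brachial Hox genes, which mark position along the neck and forelimb levels, had a median of 0.76 over 5 members in the authors' deposited table (cameraPR adjusted p = 1.82e-05), with 1 risen over all genes and 2 adjusted over the list alone. The gene that rose was HOXC4, by 0.61 (adjusted p = 0.025), beside HOXB7 at 0.85 (adjusted p = 0.885) and HOXB8 at 0.76 (adjusted p = 0.963) in the authors' deposited table. Skeletal muscle genes had a median of 0.31 over 12 members in the authors' deposited table (cameraPR adjusted p = 0.000603), with none risen over all genes and 1 adjusted over the list alone, and MYH15 stood at 0.64 (adjusted p = 0.170). Cholesterol synthesis (13 members, median 0.16) and cell cycle genes (26 members, median 0.08) were higher as lists in the authors' deposited table (cameraPR adjusted p = 0.0412 for each), with 0 members called by either count. Both calls ended at a preset correlation of 0.05 (adjusted p = 0.177 and 0.233), and neither passed on ranks (adjusted p = 0.1003 and 0.0537). Posterior Hox genes, tested at day 7 alone, did not pass (5 members, median 1.59, cameraPR adjusted p = 0.168, 1 higher adjusted over the list alone in the authors' deposited table). In all, 35 lists were tested at day 7 and 30 did not pass. Among these were neural progenitors and nicotinic receptor subunits (cameraPR adjusted p = 0.672 for each) and neuronal differentiation and cytoskeleton (cameraPR adjusted p = 0.978).

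Other named genes of day 7 came from both sources. KCNJ2, THBS4 and CFAP52 fell, with log2 fold changes of -0.59, -0.40 and -1.96 in the authors' deposited table (adjusted p = 0.0341, 0.0215 and 0.0357), and AGFG1 rose by 0.37 (adjusted p = 0.0294). The genes TAT, PROC, HGFAC, F9, FGG, FAM3D and UPK3A passed with log2 fold changes over 10 in size in the authors' deposited table, 4 higher and 3 lower. In the matrix 6 of them had 3 to 14 counts over the 4 libraries of the higher group and 0 in the other, and FGG was not found by its identifier, so no fold is given for them. CHRNA3, CHRNA4 and CHRNB2 stood at 0.49, 0.10 and -0.13 in the authors' deposited table (adjusted p = 0.9996 for each). In the matrix MMP11 (ENSGALG00000005968) had 17.2 ± 4.58 CPM in vehicle and 8.57 ± 1.32 CPM in nicotine libraries (SD, n = 4 each), a log2 fold change of -1.003 with a standard error of 0.19 (edgeR adjusted p = 0.426), and the ranges of the groups did not overlap. CFAP52, IMPG2, SLC25A34 and MACC1 stood at log2 -1.99, -1.86, -0.94 and -1.75 without passing (edgeR adjusted p = 0.905 for the first and 1 for the rest). GHRL and ANKRD33B stood at log2 0.78 and 0.89 without passing (edgeR adjusted p = 1 for each). SYPL1 and SULT1C3 had 2 counts each in the vehicle libraries of day 7, all in replicate 2, so no fold is given for them. In nicotine libraries they had 0.272 ± 0.136 and 0.695 ± 1.14 CPM (SD, n = 4 each) and did not pass (edgeR adjusted p = 0.905 and 1). For SULT1C3 that mean rests on replicate 2, at 2.40 CPM against 0 to 0.272 in the others. OR11A1 had 0 counts in the 4 vehicle libraries of day 7 and 0 to 14 in nicotine libraries, where its level was 0.294 ± 0.249 CPM (SD, n = 4). Its mean was 2.57-fold higher with 3 counts per library as the floor (edgeR adjusted p = 0.905), but the groups meet at 0 counts. OR11A1 passed as higher in the authors' deposited table (adjusted p = 0.004), whose fitted log2 fold change of 5.38 is no bound. DESeq2 on the matrix called MMP11 and OR11A1 (DESeq2 adjusted p = 0.000869 and 0.00853). With a covariate for the 57 absent loci, or without nicotine day 5 replicate 3, it also called CFAP52 and IMPG2 (DESeq2 adjusted p = 0.0213 to 0.0378).

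**Figure D3:**
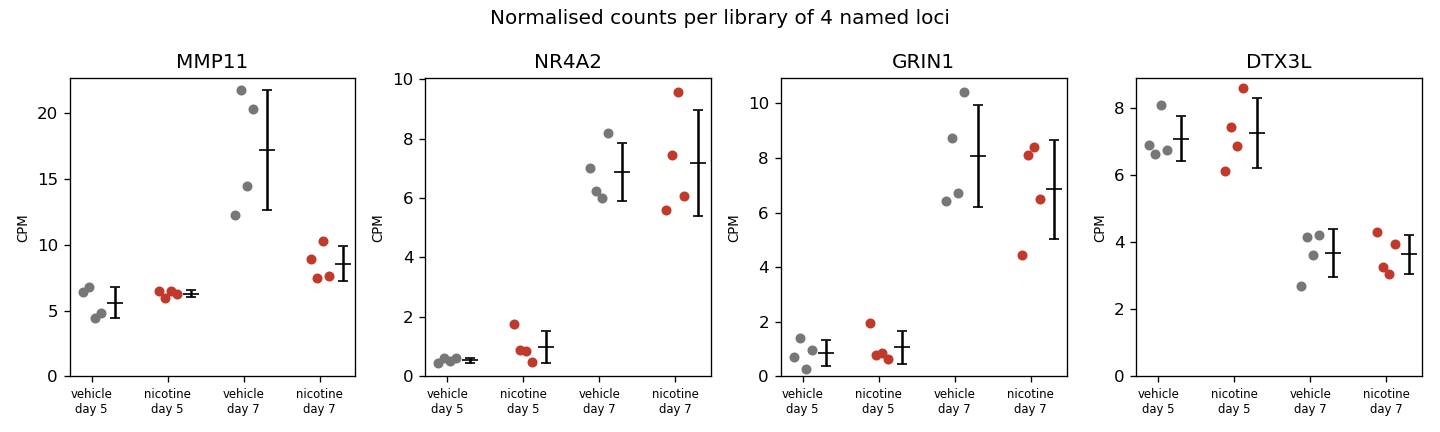
CPM per library of MMP11, NR4A2, GRIN1 and DTX3L, with the mean and SD of each group of 4 beside its points. MMP11 is at 17.2 CPM in vehicle and 8.57 CPM in nicotine libraries of day 7, while NR4A2 and GRIN1 are higher and DTX3L lower at day 7 under both treatments.

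From day 5 to day 7, genes of synapses and axon guidance rose in vehicle embryos while genes of cell division and ribosomes fell. edgeR called 6844 loci, 3231 higher and 3613 lower at day 7, or 3421 and 3427 with RLE normalisation and 3694 and 3649 by DESeq2. The authors' deposited table lists 7533, with 3705 higher and 3828 lower. On the 8 compared libraries alone edgeR called 3168 higher and 3083 lower, and DESeq2 with a covariate for the 57 absent loci called 3712 and 3806. Which direction held more loci thus depended on the settings of either tool. NR4A2 (ENSGALG00000012538), a nuclear receptor of neurons, rose from 0.544 ± 0.0817 to 6.87 ± 0.982 CPM (SD, n = 4 each), a log2 fold change of 3.64 with a standard error of 0.33 (edgeR adjusted p = 1.02e-05). GRIN1 (ENSGALG00000008898), an NMDA receptor subunit, rose from 0.844 ± 0.475 to 8.07 ± 1.87 CPM (SD, n = 4 each), a log2 fold change of 3.23 with a standard error of 0.44 (edgeR adjusted p = 7.74e-05). DTX3L (ENSGALG00000012075), a ubiquitin ligase, fell from 7.08 ± 0.670 to 3.67 ± 0.711 CPM (SD, n = 4 each), a log2 fold change of -0.95 with a standard error of 0.17 (edgeR adjusted p = 0.000619).

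Synapse, axon guidance and dorsal root ganglia genes were higher at day 7 in vehicle embryos. Of 16 synapse and neurotransmitter genes, 14 rose and 1 fell, also adjusted over the list alone, with a median of 1.57 in the authors' deposited table (cameraPR adjusted p = 1.49e-08), as for GRIA2 at 1.75 (adjusted p = 8.13e-17) and STX1A at 1.64 (adjusted p = 1.10e-12). Of 27 axon guidance genes, 19 rose and 0 fell (20 and 1 adjusted over the list alone), with a median of 0.60 in the authors' deposited table (cameraPR adjusted p = 2.29e-05). Genes of dorsal root ganglia and neural crest rose in 8 of 11 cases, or 9 adjusted over the list alone, with a median of 0.93 in the authors' deposited table (cameraPR adjusted p = 0.0038). Of 11 genes of neuronal differentiation and cytoskeleton, 5 rose, also adjusted over the list alone, with a median of 0.64 in the authors' deposited table (cameraPR adjusted p = 0.0178, and 0.0603 at a preset correlation of 0.05). Astroglial genes rose in 4 of 8 cases, or 5 adjusted over the list alone, with a median of 0.28 in the authors' deposited table (cameraPR adjusted p = 0.0459). The astroglial call ended at a preset correlation of 0.05 (adjusted p = 0.0966), on ranks (adjusted p = 0.128) and after removal of the span trend (adjusted p = 0.0672).

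Proliferation and ribosomal genes were lower and skeletal tissue genes higher at day 7 in vehicle embryos. All 26 measured cell cycle genes fell, also adjusted over the list alone, with a median of -0.79 in the authors' deposited table (cameraPR adjusted p = 1.34e-14), with CCNA2 at -0.68 and RRM1 at -0.73. Of 46 ribosomal protein genes, 36 fell and 0 rose (37 fell adjusted over the list alone), with a median of -0.51 in the authors' deposited table (cameraPR adjusted p = 7.43e-08). Cartilage and sclerotome genes rose in 6 of 12 cases, or 7 adjusted over the list alone, with a median of 1.31 in the authors' deposited table (cameraPR adjusted p = 0.00515), and ACAN, the main cartilage proteoglycan, rose by 2.61. Connective tissue and meninges genes rose in 8 of 12 cases and fell in 1, also adjusted over the list alone, with a median of 0.64 in the authors' deposited table (cameraPR adjusted p = 0.0156, and 0.0603 at a preset correlation of 0.05).

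The remaining 25 lists tested did not pass in vehicle embryos, and each is given with its median log2 fold change and cameraPR adjusted p from the authors' deposited table. Cell lineage lists were oligodendrocyte lineage (0.72, adjusted p = 0.0724), spinal interneuron transcription factors (1.34, adjusted p = 0.132), motor neurons and cholinergic transmission (0.27, adjusted p = 0.284), neural progenitors (-0.24, adjusted p = 0.614) and brachial Hox genes (-0.43, adjusted p = 0.828). Signalling lists were BMP pathway and roof plate (0.50, adjusted p = 0.145), Sonic hedgehog pathway (0.15, adjusted p = 0.177), Wnt pathway (0.22, adjusted p = 0.177), retinoic acid pathway (-0.57, adjusted p = 0.210), Notch pathway (0.29, adjusted p = 0.291) and nicotinic receptor subunits (0.68, adjusted p = 0.177). Stress and metabolic lists were oxidative stress response (-0.27, adjusted p = 0.133), unfolded protein and integrated stress response (-0.21, adjusted p = 0.205), cholesterol synthesis (-0.08, adjusted p = 0.726), neural tube closure and folate metabolism (-0.15, adjusted p = 0.726), xenobiotic and nicotine metabolism (0.06, adjusted p = 0.828), heat shock and immediate early genes (0.25, adjusted p = 0.8288), hypoxia and glycolysis (0.05, adjusted p = 0.906) and apoptosis and p53 targets (-0.09, adjusted p = 0.993). Other cell types were endothelium (0.29, adjusted p = 0.140), epidermis (-0.34, adjusted p = 0.541), notochord and floor plate (0.17, adjusted p = 0.726), skeletal muscle (-0.03, adjusted p = 0.726), macrophages and leukocytes (-0.18, adjusted p = 0.793) and erythroid cells (0.00, adjusted p = 0.993). For skeletal muscle the test pointed up while the median was negative. Oligodendrocyte lineage passed only after removal of the span trend (cameraPR adjusted p = 0.0431). Single genes of these lists did pass in the authors' deposited table: CHRNA4 and CHRNB2 rose by 0.56 and 0.80 (adjusted p = 0.00591 and 0.0232), and CYP26A1, which degrades retinoic acid, fell by 1.42.

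Further genes with large changes in vehicle embryos were not tested as a group. In the matrix OTOF, SGIP1, ADAMTS2, ADCY8, DSCAML1, MGAT4C, LHX2 and FBXO41 rose by 2.46 to 5.94 on the log2 scale (edgeR adjusted p = 4.68e-05 to 0.00967). The largest values, 5.94 for OTOF and 4.53 for SGIP1, rest on 0 to 2 and 0 to 6 counts per vehicle library of day 5, so their size is uncertain. PTPRQ, ESYT3, CD247, AMPD1, ART4, TXLNB, LCP2, AMDHD1 and DGKB had log2 fold changes of -4.22 to -0.54 (edgeR adjusted p = 0.000165 to 0.03). The -4.22 of PTPRQ rests in part on vehicle day 5 replicate 3, at 29.9 CPM against 3.82 to 6.59 in the others, and without it the value was -3.07 (edgeR adjusted p = 0.000118). ESYT3 went from -3.08 to -2.46 without vehicle day 5 replicate 1. Some calls ended with 1 vehicle library left out. They were TXLNB without day 5 replicates 2 or 3 or day 7 replicates 1 or 2, and LCP2 without day 7 replicates 2 or 3 (edgeR adjusted p = 0.0532 to 0.0862). AMDHD1 ended without day 5 replicates 1 or 3 or day 7 replicates 1, 2 or 3, and DGKB without day 5 replicates 1 or 3 or day 7 replicates 3 or 4 (edgeR adjusted p = 0.0503 to 0.0723). Among the largest increases in the authors' deposited table were those of GLRA2, OTOF (4 counts over the vehicle libraries of day 5 in the matrix) and SLC25A47, at log2 5.75 to 7.73. GLRA2 and SLC25A47 were not found in the matrix by their identifiers, so the counts behind their folds could not be checked. FSHB, HEPACAM, DGKG, IQCJ, ANO4, ZPLD1 and VSTM2A were listed beside them, with 0 to 2 counts over the vehicle libraries of day 5 in the matrix, so no fold is given for them. C7, ALDH1A1 and TDRD1 were among the largest decreases in the authors' deposited table, at log2 -5.23 to -4.70, with 4 to 8 counts over the vehicle libraries of day 7 in the matrix. SULT1C3, TMEM52B, GPR143, SYPL1 and FAM83A were listed with them and had 0 to 2 counts there, so no fold is given. OR11A1, with 0 counts in the vehicle libraries of day 7, was at least 10.4-fold lower there than at day 5 in the matrix, with 3 counts per library as the floor.

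**Figure D4:**
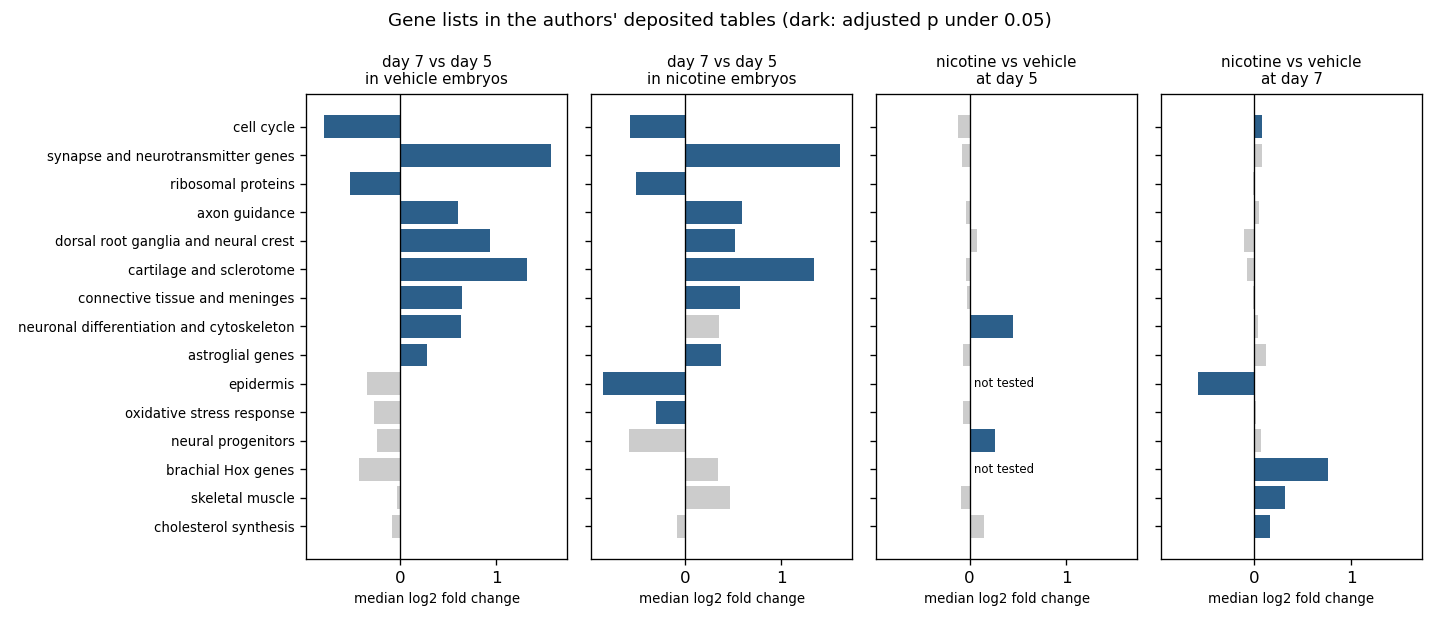
Median log2 fold change in the authors' deposited tables of each list that passed in at least 1 of 4 comparisons, with dark bars for a cameraPR adjusted p under 0.05 and grey bars for lists that did not pass. Synapse genes stand at 1.57 and 1.61 and cell cycle genes at -0.79 and -0.56 for day 7 against day 5 in vehicle and nicotine embryos.

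In nicotine embryos, synapse and axon guidance genes also rose from day 5 to day 7 and cell cycle and ribosomal genes fell. edgeR called 5451 loci, 2417 higher and 3034 lower, and the authors' deposited table lists 6107, with 3110 higher and 2997 lower. With RLE normalisation the edgeR counts were 2732 higher and 2604 lower, and DESeq2 gave 3044 and 2861, so which direction held more loci depended on the settings. Genes that were higher were long: in the authors' deposited table those called higher had a median span of 49.6 kb and those called lower 10.3 kb. The rank correlation of span with the log2 fold change was 0.381 there, against 0.116 in vehicle embryos. This contrast uses the nicotine libraries of day 5, in which long genes were low, so it partly restates the difference of day 5. In the matrix the correlation over 663 genes was 0.257 in nicotine embryos, and 0.194 without nicotine day 5 replicate 3. Of 16 synapse and neurotransmitter genes, 14 rose and 0 fell, also adjusted over the list alone, with a median of 1.61 in the authors' deposited table (cameraPR adjusted p = 2.04e-10). Axon guidance genes rose in 20 of 27 cases, or 22 adjusted over the list alone, with a median of 0.59 in the authors' deposited table (cameraPR adjusted p = 3e-06). Of 46 ribosomal protein genes, 40 fell (43 adjusted over the list alone), with a median of -0.51, and 22 of 26 cell cycle genes fell (23 adjusted over the list alone), with a median of -0.56 in the authors' deposited table (cameraPR adjusted p = 5.15e-14 and 5.82e-12). After removal of the span trend these 4 lists still passed (cameraPR adjusted p = 7.07e-08 for synapse, 0.022 for axon guidance, 1.86e-07 for ribosomal and 3.09e-11 for cell cycle genes). Cartilage and sclerotome genes rose in 8 of 12 cases and astroglial genes in 4 of 8, both also adjusted over the list alone, with medians of 1.34 and 0.38 in the authors' deposited table (cameraPR adjusted p = 0.00117 and 0.00444). Of the 34 lists tested, 24 did not pass, among them neuronal differentiation and cytoskeleton, with 2 of 11 genes risen, also adjusted over the list alone, and a median of 0.36 in the authors' deposited table (cameraPR adjusted p = 0.366).

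Calls for lower epidermal and antioxidant genes at day 7 in nicotine embryos depended on the settings of the test. Of 5 epidermis genes, 4 fell, also adjusted over the list alone, with a median of -0.84 in the authors' deposited table (cameraPR adjusted p = 0.0255, and 0.0515 at a preset correlation of 0.05), and EPCAM fell by 1.45. Of 17 oxidative stress response genes, 9 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.30 in the authors' deposited table (cameraPR adjusted p = 0.0255). The antioxidant call ended at a preset correlation of 0.05 (adjusted p = 0.108) and after removal of the span trend (adjusted p = 0.136). Dorsal root ganglia and neural crest genes rose in 4 of 11 cases and connective tissue and meninges genes in 7 of 12, both also adjusted over the list alone, with medians of 0.52 and 0.58 in the authors' deposited table (cameraPR adjusted p = 0.016 and 0.0176). These calls ended at a preset correlation of 0.05 (adjusted p = 0.0515 and 0.0576). CHRNA3 and CHRNA4 rose by 0.93 and 0.68 in the authors' deposited table (adjusted p = 0.0162 and 0.000742), CHRNB2 stood at 0.32 (adjusted p = 0.471), and the list of nicotinic receptor subunits did not pass (10 members, cameraPR adjusted p = 0.084). It passed as higher on ranks (adjusted p = 0.0454) and after removal of the span trend (adjusted p = 0.0065). Neural progenitors passed as lower on ranks alone (adjusted p = 0.0341). After removal of the span trend alone, lists that passed in nicotine embryos were skeletal muscle and oligodendrocyte lineage, higher, and the retinoic acid pathway, lower (cameraPR adjusted p = 0.000818, 0.0203 and 0.0317).

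Among single loci of the nicotine embryos, NR4A2 rose from 0.994 ± 0.544 to 7.17 ± 1.78 CPM (SD, n = 4 each), a log2 fold change of 2.84 with a standard error of 0.31 (edgeR adjusted p = 5.76e-05). DTX3L fell from 7.25 ± 1.04 to 3.64 ± 0.584 CPM (SD, n = 4 each), a log2 fold change of -0.99 with a standard error of 0.17 (edgeR adjusted p = 0.000727). SPTBN5, MGAT4C, DLGAP1, GRIN1, HKDC1, GRIN2A, SGIP1 and SCN1A rose by 2.33 to 3.06 on the log2 scale (edgeR adjusted p = 6.36e-05 to 0.0109). PTPRQ, ESYT3, EPHA1, ENTPD3, SYK, GJB1, ACOX2, ART4 and FOXA1 had log2 fold changes of -3.47 to -0.68 (edgeR adjusted p = 0.00106 to 0.0409). Without day 5 replicates 4, 2, 3 and 1 in turn, MGAT4C, HKDC1, GRIN2A and SGIP1 went from 3.02, 2.63, 2.51 and 2.45 to 3.73, 3.34, 3.11 and 3.17. Some calls ended with 1 nicotine library left out. They were SYK without day 5 replicate 4, at -0.77 in place of -1.23, and ENTPD3 without day 5 replicate 4 or day 7 replicates 1 or 4 (edgeR adjusted p = 0.0646 to 0.0756). GJB1 ended without day 5 replicates 2 or 4 or day 7 replicates 1, 2 or 4, and ART4 without replicates 1, 2 or 4 of either day (edgeR adjusted p = 0.0562 to 0.121). FOXA1 ended without any of the 8 except day 7 replicate 4 (edgeR adjusted p = 0.0598 to 0.117). With all 8 nicotine libraries in place, ART4 and FOXA1 also ended with RLE normalisation (edgeR adjusted p = 0.0537 and 0.053) and without the filter on low counts (edgeR adjusted p = 0.0638 and 0.0657). ART4 ended on the 8 compared libraries alone (edgeR adjusted p = 0.0582) and by DESeq2 with and without the covariate (DESeq2 adjusted p = 0.0635 and 0.0535). FOXA1 ended by DESeq2 without nicotine day 5 replicate 3 (DESeq2 adjusted p = 0.0614). Increases among the largest in the authors' deposited table were those of MATN3, RELL2 and HOXC6, at log2 4.15 to 4.73, and decreases among the largest were those of GATA4, FOXI3, LIN28A, TEKT2, ALDH1A1, LRRC2 and CLUL1, at log2 -5.07 to -3.54. MFNG, FSHB, BEST3, HEPACAM, LSMEM1, IQCJ and RIT2 were listed as increases with 0 to 2 counts over the nicotine libraries of day 5 in the matrix, and RPL3L and SLC17A8 as decreases with 0 at day 7, so no fold is given for them. LIN28A, an RNA-binding protein of early embryonic cells, fell by 4.83 in the authors' deposited table (adjusted p = 3.88e-20). MATN3, HOXC6, GATA4, LIN28A and TEKT2 were not found in the matrix by their identifiers, so the counts behind their folds could not be checked.

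Whether the nicotine effect differed between the days was tested as a contrast of its own. The authors' deposited table lists 285 loci, 198 with a more positive effect at day 7 and 87 with a more negative effect, and 176 carried a symbol. The rank correlation of span with the log2 difference was 0.371 in the authors' deposited table. Immediate early genes were among the latter, with JUN at -0.61, DUSP1 at -0.71 and KLF2 at -0.94 in the authors' deposited table (adjusted p = 0.0228, 0.0218 and 0.0205). EPHA3 and SEMA3C stood at 1.04 and 0.92 (adjusted p = 0.0118 and 0.0205), DLX1 at -2.49 (adjusted p = 0.0123) and MMP11 at -1.13 (adjusted p = 0.0205) in the authors' deposited table. edgeR called 0 loci (smallest adjusted p = 0.0956), with 2521 at an unadjusted p under 0.05 against 919.7 if p were uniform. Other splits gave at most 2684, and 5 of 100 splits, counting the real one, were as large. DESeq2 called 243. With 1 library left out DESeq2 called 57 to 757, and it stayed within 1.5 times of 243 only without nicotine day 5 replicate 4, vehicle day 7 replicates 1 or 3 or nicotine day 7 replicate 4.

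None of the 30 lists tested passed for this difference. After removal of the span trend the Wnt pathway passed as lower and cell cycle and skeletal muscle as higher (cameraPR adjusted p = 0.011 each). The smallest list value was that of neuronal differentiation and cytoskeleton, with a median of -0.39 over 10 members in the authors' deposited table (cameraPR adjusted p = 0.0668) and no member called by either count. Of 12 genes of heat shock and immediate early genes, 3 were called lower, also adjusted over the list alone, in the authors' deposited table (cameraPR adjusted p = 0.104). CHRNA4 and CHRNB2 stood at 0.12 and -0.49 in the authors' deposited table (adjusted p = 0.806 and 0.524), and CHRNA3 at 0.51 without an adjusted value. The most positive values in the authors' deposited table were those of GNA13, MCU, RYR3, COL8A1, TRDN, ABHD13, LAMB4, PALMD, SBF2 and SLC24A4, at log2 1.09 to 2.10. DLX1, PTX3, DDIT4, CARMIL3, SHISA4, DRP2, TNS1, STK32B, MMP11 and FOXF2 had the most negative values in the authors' deposited table, at log2 -2.49 to -0.97. In the matrix OR11A1, MLIP, GHRL, LCP2 and HHIPL2 had the smallest p among positive values and FEV, MMP11, CNGA4, SLC25A34 and CFAP52 among negative ones, none of which passed with edgeR (edgeR adjusted p = 0.237 to 0.281). DESeq2 called MMP11 (DESeq2 adjusted p = 0.0202) and gave the others no adjusted p. It called with a covariate for the 57 absent loci MMP11, OR11A1, FEV and CNGA4 (DESeq2 adjusted p = 0.0163 to 0.0294), and without nicotine day 5 replicate 3 OR11A1 (DESeq2 adjusted p = 0.0382). This contrast and that of day 5 use the same nicotine and vehicle libraries of day 5, so their values are not independent.

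Loci called at both days were also counted. edgeR called none at either day, so 0 were shared (2747 and 858 loci at an unadjusted p under 0.05), and DESeq2 shared 1 in the same direction among its 264 and 31 calls (Fisher's exact p = 0.263, two-sided). Across 18394 loci the log2 fold changes of the 2 days, which share no library, had a correlation of -0.0106. Genes are not independent replicates, so no p is attached to this value.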

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

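The long minus short score and its difference between days, the tests of a single library, of handling, of the epidermis list, of the facial and forebrain lists and their other settings, of embryo sex, of splits with a covariate for the 57 absent loci, of the fit behind the authors' tables and of the score with libraries left out were chosen after the result was seen, as was the use of the mean in the test of delayed development.

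The difference between nicotine and vehicle libraries in the long minus short score was 0.496 higher at day 7 than at day 5 (exact permutation p = 0.00857, two-sided, over 4900 assignments within days). Without nicotine day 5 replicate 3 it was 0.315 (exact permutation p = 0.0155), and with each other library left out it was 0.451 to 0.590 (exact permutation p = 0.00286 to 0.0412). The score was chosen after long genes were seen to be lower at day 5 and is taken from the same libraries, so these p values partly restate that observation and are no independent test of a difference between days. The assignments within days also assume no nicotine effect at either day, so these p values do not test whether the effects of the days are equal. Whether treatment or handling of the groups lies behind the difference was not separated. The authors' deposited table of the difference between days lists 285 loci.

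Long genes were lower with nicotine at day 5, and 3 explanations were weighed. A single library is not the whole cause, since without nicotine replicate 3 the rank correlation of span with the edgeR difference over 663 genes was -0.185, against -0.284 with it. A delay of the nicotine embryos should give a correlation under -0.1 between the day 5 difference and the change over time in vehicle embryos, a bound set before, and with different vehicle libraries on each side the lowest of 6 values lay only just above it, at -0.0937, while the mean was 0.0501 and the highest 0.117, which argues against a delay as the whole cause. A difference in handling or RNA quality could lower long transcripts too and stays open: no measure of RNA quality was at hand, and the separation of the groups by the score (exact permutation p = 0.0286, the smallest possible, and 0.229 adjusted over 8 tests) is the pattern itself and decides nothing about its cause. An effect of nicotine itself stays open beside it, and the neuronal, progenitor and RYR3 results of day 5 rest on the same libraries.

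DLX1, DLX5 and DLX6 were lower with nicotine at day 7, while DLX2 and DLX3 did not pass in the authors' deposited table (-1.88 and -1.58, adjusted p = 0.348 and 0.121), and tissue from outside the spinal cord in the vehicle pieces was weighed as a candidate explanation. After DLX genes and EMX2, LHX6, LHX8, OSR2 and PRRX1 had been seen lower, 14 other facial and pharyngeal arch genes and 15 other forebrain genes, with 0 members in the other lists, were written down before their own values were looked at, so the lists hold none of the genes that led to them but are not independent of that observation. In the authors' deposited table, 9 of 10 measured facial genes were lower, with a median of -0.61 (interval over genes -1.38 to -0.06, cameraPR p = 1.26e-05), as were 6 of 7 forebrain genes, with a median of -0.86 whose interval of -4.32 to 0.32 includes 0, so this list is the weaker support (cameraPR p = 0.0119), both p unadjusted, and 0 of either list passed singly, while at a preset correlation of 0.05 these p were 0.000152 and 0.0231, on ranks 0.000323 and 0.0218, and after removal of the span trend 1.6e-05 and 0.0485. The epidermis list was lower too (cameraPR adjusted p = 6.18e-06), and brachial Hox and skeletal muscle lists were higher (cameraPR adjusted p = 1.82e-05 and 0.000603). Cartilage and sclerotome and connective tissue and meninges did not pass (medians -0.07 and -0.02, cameraPR adjusted p = 0.728 and 0.489). Nor did endothelium or dorsal root ganglia and neural crest (medians -0.0003 and -0.11, cameraPR adjusted p = 0.672 and 0.58). A different level of dissection or different amounts of neighbouring tissue may account for part of the pattern, though not every list of such tissue passed. Several genes of this pattern are also active in limb and neck tissue, no limb list was tested and the tables give no levels, so the source was not identified, and an effect of nicotine on these genes stays open.

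The 57 loci missing from 1 library in each group may mark embryo sex, which the labels do not give. No other pattern of absence in 1 library per group held more than 1 locus. Male birds carry a pair of Z chromosomes and no W, so libraries without W-linked transcripts should have more from Z-linked genes. Across all groups the lowest of the 4 was 0.0275 under the highest of the other 12 (a difference of -0.0275 log2), which did not meet the first prediction. A comparison within groups, added afterwards, found the library lacking the loci highest in each of the 4 groups, by at least 0.256 log2 over 55 Z-linked genes.

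Other splits of the libraries were tested for each count. Chance is an unlikely source of the time counts: edgeR called 6844 loci in vehicle and 5451 in nicotine embryos, against at most 1 and 3 in other splits, and 1 of 35 splits reached each real count. That is the smallest share that 35 splits can give. Each other split mixes the days within its groups, which widens their spread and lowers its calls. For nicotine edgeR called 0 loci at day 5, at day 7 and for the difference between days, so all 35, 35 and 100 splits were as large by construction and decide nothing, with at most 72, 1 and 5 in the others. DESeq2 called 264, 31 and 243, other splits reached 1603, 242 and 504, and 6 of 35, 5 of 35 and 3 of 30 were as large, so chance could not be excluded for these counts.

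Loci at an unadjusted p under 0.05 give another count of the same splits. With edgeR they were 2747, 858 and 2521 at day 5, at day 7 and for the difference, against at most 3915, 867 and 2684, and 7 of 35, 2 of 35 and 5 of 100 splits were as large. With DESeq2 they were 2939, 1015 and 2802, against at most 4168, 1006 and 2903, and 8 of 35, 1 of 35 and 3 of 30 were as large. The count of DESeq2 at day 7 was above all other splits only by 1015 to 1006. With a covariate for the 57 absent loci it was not (1199, 2 of 35 as large, at most 1272 in the others), nor was the number of calls, so chance is left open at day 7 too.

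Splits that call several times the real count may point to a structure of the samples. The day 5 split with most DESeq2 calls without a covariate (1603) set vehicle replicates 1 and 3 and nicotine replicates 2 and 4 against the rest. These were the lowest of that day on the first principal component, which separates the days, at -70.2 to -43.9 against -43.6 to -22.7. What this spread within day 5 stands for was not tested. The 57 absent loci were the 1 candidate tested. With a covariate for them in each split, DESeq2 called 404, 179 and 281 loci, others reached 2170, 404 and 960, and 6 of 35, 3 of 35 and 5 of 30 were as large. edgeR with it called 1, 0 and 1, others reached 533, 0 and 3, and 12 of 35, 35 of 35 and 29 of 100 were as large, where the count of 0 (890 at an unadjusted p under 0.05, against 179 calls by DESeq2) again decides nothing. Chance was thus not excluded for the counts with the covariate either, and splits with many calls were still there. The log2 fold changes of the authors' deposited tables lay within 0.01 of this DESeq2 fit at 99.3% to 99.7% of 3104 loci, against at most 62.2% without the covariate. The authors' 322, 84 and 285 calls could not be split themselves. Their log2 fold changes come close to this fit, but their calls differ from its 404, 179 and 281. At the 3104 loci the tables call 15, 13 and 20 and the fit 25, 16 and 23, with 13, 13 and 16 in both. Chance was thus not excluded for the authors' calls or for the nicotine results on named genes and gene lists that rest on the authors' tables. Among splits that place the libraries lacking the loci evenly, 3 of 20, 3 of 20 and 1 of 9 were as large for DESeq2 (at most 1758, 404 and 101 in the others), where so few splits cannot give a share under 0.05, and 6 of 20, 20 of 20 and 10 of 29 for edgeR (at most 52, 0 and 3).

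An earlier run with the 8 compared libraries alone gave edgeR 0 and 5 loci at days 5 and 7, against 4 and 278 in other splits, and DESeq2 20 and 94 against 415 and 451. For the time comparisons it gave edgeR 6251 loci in vehicle and 5114 in nicotine embryos, against at most 3 and 257 in other splits, and 1 of 35 reached each. The fit of all 16 libraries planned in the design replaced it after its outcome had been seen.

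Single libraries lay far from the rest of their group in 10 of 153 sets of values, where chance gives 1 in 20, or 7.65. The sets came from named loci and from library measures such as total counts, and all 10 were of named loci. The gap divided by the range of the group was 0.918 for LCP2 in vehicle day 5 replicate 1 (3.00 against 2.78 to 2.80 CPM) and 0.894 for PTPRQ in vehicle day 5 replicate 3 (29.9 against 3.82 to 6.59 CPM). It was 1 for SYPL1 and 1 for SULT1C3 in vehicle day 7 replicate 2, each at 0.0744 CPM against 0 in the others, a value that any set with 1 library above 0 gives. SULT1C3 in nicotine day 7 replicate 2 gave 0.887 (2.40 against 0 to 0.272 CPM), and PTPRQ in nicotine day 7 replicate 1 gave 0.928 (0.619 against 0.317 to 0.339 CPM). AMPD1 in vehicle day 7 replicate 3 gave 0.877 (1.91 against 0.922 to 1.04 CPM), and CNGA4 in vehicle day 7 replicate 4 gave 0.868 (1.13 against 1.38 to 1.41 CPM). GRIN1 in nicotine day 5 replicate 1 gave 0.849 (1.97 against 0.653 to 0.852 CPM), and SYK in nicotine day 5 replicate 4 gave 0.870 (5.05 against 1.80 to 2.22 CPM).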

How the results depend on the processing

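The tests with a covariate for the 57 absent loci, robust estimates, library weights, DESeq2 without a library, another threshold for the authors' tables and other settings for the lists were chosen after the data were seen. The cause of the changes below was not tested. The counts over time stayed within 1.5 times under every alternative run, at 5494 to 7013 in vehicle and 4033 to 5233 in nicotine embryos with each library left out.

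The nicotine counts of edgeR were 0 at both days and for the difference between days (2747, 858 and 2521 at an unadjusted p under 0.05). DESeq2 called 264, 31 and 243 loci, with that covariate 404, 179 and 281, and without nicotine day 5 replicate 3 it called 57, 34 and 98. With each library of the comparison left out in turn DESeq2 called 35 to 1181, 24 to 71 and 57 to 757. edgeR with the replicate number as a block called 1 locus at day 5 and 1 for the difference, although the numbers do not pair the libraries, and the same covariate gave 1 and 1, also with robust estimates. limma voom with library weights and that covariate called 2 at day 7 and 1 for the difference, and edgeR on the 8 compared libraries called 5 at day 7. With each library left out edgeR called 0 to 3 at day 5, 0 to 1 at day 7 and 0 to 5 for the difference. At day 5 it called 3 without vehicle replicate 4, and 1 without vehicle replicate 1, vehicle replicate 2, nicotine replicate 1 or nicotine replicate 3. At day 7 it called 1 without nicotine replicate 1. For the difference it called 5 without vehicle day 5 replicate 4, and 1 without vehicle day 5 replicate 2, nicotine day 5 replicate 3, vehicle day 7 replicate 3 or nicotine day 7 replicate 1. DESeq2 shared 1 call between days, edgeR 0.

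Lists that passed went from 2 to 1 at day 5, from 5 to 3 at day 7 and from 10 to 6 over time in nicotine embryos at an inter-gene correlation of 0.05, and from 5 to 3 at day 7 on ranks. Over time in vehicle embryos they went from 9 to 6 at that correlation and to 8 on ranks. With the span trend removed the difference between days went from 0 to 3 lists (Wnt pathway, cell cycle and skeletal muscle). At an adjusted p under 0.1 the authors' deposited tables list 765 loci at day 5 and 599 for the difference. Among named loci of the matrix 707 values kept direction and call, 22 passed newly and 8 no longer passed (5 of ART4 and 3 of FOXA1, over time in nicotine embryos), and with single libraries left out 603 kept both and 37 no longer passed. The 40 called in the main edgeR fit were all of the time comparisons. The 30 of the nicotine comparisons were not called there, so a kept call means that they still did not pass. Genes named only from the authors' deposited tables, such as DLX1, HOXC4, ISL1 and RYR3, were not covered. No named locus changed sign under the alternatives run.

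DESeq2 gave no adjusted p to the named loci of day 5, nor to those of the difference other than MMP11. Not run were the W-linked covariate, the removal of haemoglobin genes and the shares of other cell types, whose genes the matrix does not name, and for lists the estimated correlation, RLE scaling, the block and single libraries left out. On simulated counts of this size edgeR recovered 57% of 2-fold and 14% of 1.5-fold changes at day 5, and 55% and 25% at day 7. Changed loci were all above a minimum mean level, and neither depth nor replication was varied.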

Other observations

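The change of the 5 listed DLX genes over time was compared between treatments. In the authors' deposited table DLX1, DLX3, DLX5 and DLX6 rose from day 5 to day 7 in vehicle embryos, by 1.59, 1.26, 1.42 and 2.49 (adjusted p = 0.000797, 0.0196, 0.00721 and 0.000238), and DLX2 stood at 1.07 (adjusted p = 0.184). In nicotine embryos DLX1, DLX5 and DLX6 stood at -0.90, -0.54 and -0.23 and DLX2 and DLX3 at -1.02 and 0.13 in the authors' deposited table (adjusted p = 0.0976, 0.410, 0.838, 0.232 and 0.879). The test of the difference passed for DLX1 alone in the authors' deposited table, with an adjusted p of 0.0123 against 0.0734 for DLX5, 0.062 for DLX6 and 0.181 for DLX2, while DLX3 has no adjusted value there. DLX1, DLX5 and DLX6 led to this comparison by their difference at day 7, and all these contrasts share libraries of day 7 with it, so the values partly restate that choice and are not independent of it.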
